A study of Mus musculus with 24 samples.

How the data were processed

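Total RNA from the medial prefrontal cortex of mice was extracted with Trizol, cleaned up and DNase-treated on RNeasy columns, checked on a Bioanalyser and made into Illumina libraries, per the labels' protocols. The 24 libraries carry 1 batch date and the genotype label 5xFAD. Sample titles give 6 groups of 4. In them SI marks socially isolated mice and EE the enriched environment that the series title names. The title also names resocialization, but the labels do not tie that word to an arm. The sources used here do not say what GH stands for, nor what WT stands for in a series whose genotype label is 5xFAD throughout, so these arms are called GH and the WT arm. Titles number the replicates 1 to 4, but the labels do not say that each library came from its own mouse, so p-values measure the spread between these samples.

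The deposited table holds whole-number read counts per gene that the authors did not normalise, as judged from the values. The submitters' processing notes name the genome build mm10. The aligner, the counting tool, the annotation release and the use of strand are not given in the sources used here. The table has 56750 entries, of which 52073 (91.8%) could be paired with a symbol. Those with no symbol hold 0.695% of reads and entered the tests under their gene ID. All 24 count columns belong to a named sample. Total counts per library ran from 33683587 to 51274917. Reads from near-identical copies (haemoglobin genes, Hspa1a and Hspa1b, processed pseudogenes such as Gm5514) or from overlapping and antisense genes could have been split by the counting, and values of those genes are uncertain. An entry is named APP in human capital spelling, with no mouse ID. It is called the human APP entry here from that spelling and the 5xFAD genotype. The sources do not say which sequence was counted for it, and reads shared between the mouse and human copies of this gene, or between mouse Thy1 and a Thy1-driven transgene, could have been counted under either. Gene positions are from GENCODE mouse release M21 (GRCm38, the assembly of mm10). Some gene IDs of the table are newer than that release.

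Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr on the group, robust dispersion, no covariate), with all 24 libraries in 1 fit so that the groups share an estimate of the spread. This left 20354 genes. Benjamini-Hochberg adjusted p under 0.05 over all genes was the threshold. By chance alone about 1018 of these genes would have an unadjusted p under 0.05. There were 10 contrasts: isolation without treatment, EE and the WT arm in each housing, isolation within EE and within the WT arm, EE against the WT arm in isolated mice, and both treatment-by-housing interactions. CPM values use TMM-scaled totals, and log2 CPM a prior count of 2. Errors are SD over n = 4 libraries unless SE is written.

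For gene lists, 32 were fixed before the data were examined: cell types of cortex (microglia in 2 states, astrocytes in 2, oligodendrocytes, precursors, interneurons, pyramidal layers, endothelial and mural cells), neighbouring tissue (meninges, choroid plexus, blood, striatum, olfactory bulb), and pathways (complement, interferon, antigen presentation, immediate early, neurotrophic, pre- and postsynaptic, GABA receptor, monoamine and peptide receptor, glucocorticoid, circadian, heat shock, amyloid processing, mitochondrially encoded, nuclear oxidative phosphorylation, ribosomal protein and sex-linked genes). They were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison. The same lists were tested with an estimated correlation, with fry, and by an exact permutation of the list's mean log2 CPM over the 70 assignments of 4 and 4 libraries, two-sided, whose smallest possible p is 0.0286. Adjusted over 32 lists, that p falls under 0.05 only where many lists share it. For the interactions, housing was shuffled within the treatment arm and within the untreated mice, with 70 assignments in each, in all combinations. That p is for no housing difference in either arm, so it does not test the interaction alone. A list with under 3 measured members was not tested. A further 3 lists (16 cerebellar, 12 forebrain pyramidal, 10 thalamus and habenula genes) were written after the principal components had been seen. Camera with the preset correlation compares a list with the other genes and does not count the spread of a whole list between libraries, which the estimated correlation and the permutation do.

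The rule for named genes, fixed beforehand, was the 10 largest rises and falls past the threshold with a mean CPM of at least 1 and a symbol not of the Gm or Rik form, up to 4 members past it per list, and App, Thy1, Cst7, Trem2, P2ry12, Gfap, Mbp, Bdnf and Fos always; where no gene passed, the 5 with the smallest p as values. Gm5514 falls outside the rule and was named after its values were seen, as were the list members given as examples, which are mostly those with the smallest p. A member that did not pass is given as a value only. Results of some items are not reported here.

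Correlations between isolation and treatment fold changes across genes share the SI_Con libraries. They are given beside 20 simulated runs with no effect, and again with the SI_Con libraries divided 2 and 2 between the contrasts, with a one-sided exact p over 34650 assignments of the 12 libraries. With divided libraries that p is for the covariance. Each step was tested on simulated counts before use. For the isolation comparison over 20354 genes, the edgeR step recovered 14% of 50 genes changed 1.5-fold, 48% of 50 changed 2-fold, 66% of 50 changed 3-fold and 74% of 50 changed 4-fold, with 5 false calls. A simulated list shift was called, with 0 of 31 others. Genes were simulated independently, so that run could not show false list calls from members that vary together between libraries.

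Alternatives fixed beforehand were RLE factors, no count filter, a filter of CPM 1 in 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, a fit of the compared groups alone, the replicate number as a block, and leaving out each library. Added after seeing the data were sex as a covariate, SI_EE library 1 left out, the 4 libraries in which longer genes read lower left out for the lists, 4 surrogate variables (sva 3.50.0), leaving out libraries for the lists, and the permutation of list means. Sex was read from Xist (over 100 CPM) and Y-linked genes (over 20 CPM). Within-group pairs of libraries differed by far more than counting noise (chi-square per degree of freedom of 28.8 to 251, over genes of at least 20 counts), so none was counted as a duplicate. Figures were drawn with matplotlib 3.10.9 in python 3.11.15.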

Results

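Gene expression was measured by bulk RNA sequencing in the medial prefrontal cortex of mice labelled 5xFAD, a strain that carries a human APP transgene with familial Alzheimer's disease mutations under the neuronal Thy1 promoter. The 24 libraries fell into 6 groups of 4: GH and socially isolated (SI) mice without treatment (GH_Con, SI_Con), with an enriched environment (GH_EE, SI_EE) and in the WT arm (GH_WT, SI_WT). Total counts per library ran from 33683587 (SI_WT 4) to 51274917 (SI_WT 1), and 20354 genes were tested.

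The human APP entry was read in every library, from 337 CPM in SI_EE 1 to 4685 CPM in SI_WT 1. In the WT arm it was at 2891 ± 462 CPM in GH_WT and 3508 ± 1164 in SI_WT (SD, n = 4), beside GH_Con (2950 ± 1013), SI_Con (1945 ± 703), GH_EE (2543 ± 944) and SI_EE (2268 ± 1516). Of the group differences tested for it, that between SI_WT and SI_Con had the smallest exact permutation p, 0.0571 (adjusted 0.457).

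The labels give no sex. Xist, the X-inactivation RNA of female cells, was read in 12 libraries and Y-linked genes in the other 12, with 3 female and 1 male library in GH_Con, 1 and 3 in SI_EE, and 2 and 2 in each other group. SI_EE 1 stood apart on the first principal component (14.3% of variance). It held transcripts of cerebellum: Gabra6, a granule cell GABA receptor subunit, at 342 CPM and Pcp2, a Purkinje cell gene, at 242 CPM, against at most 1.13 and 2.17 CPM in any other library. The mean of the cerebellar list was 7.83 log2 CPM in SI_EE 1, against a median of 0.83 and a maximum of 1.98 in the others, and that of the forebrain pyramidal list was 4.86 there and at least 6.29 elsewhere. Genes of thalamus and habenula averaged 4.49 and 4.69 log2 CPM in GH_WT 2 and GH_WT 4 and 3.69 in SI_EE 1, against at most 2.67 in the others. SI_EE 1 was the highest library for Calb2 (369 CPM) and Lhx9 (20.8 CPM). Gpr151 (0.58 CPM) and Slitrk6 (0.706 CPM) were the only genes of the list that lay there within the range of the remaining libraries. Gpr151 was at 10.2 and 6.45 CPM and Slitrk6 at 12.1 and 13.2 CPM in GH_WT 2 and GH_WT 4. Striatal genes averaged 2.58 in SI_EE 1 and 2.99 in GH_WT 1, and 4.36 to 6.03 elsewhere. Ttr, the main choroid plexus transcript, was at 1013 CPM in SI_Con 4, 522 in SI_EE 3 and 321 in GH_WT 2. Longer genes read lower in GH_Con 2, SI_Con 2, SI_Con 3 and SI_WT 4 than in the rest (Spearman's rho across genes of length and deviation from the mean −0.267, −0.357, −0.313 and −0.397), and ribosomal protein genes took 1.31%, 1.38%, 1.52% and 1.70% of their reads.

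**Figure D1:**
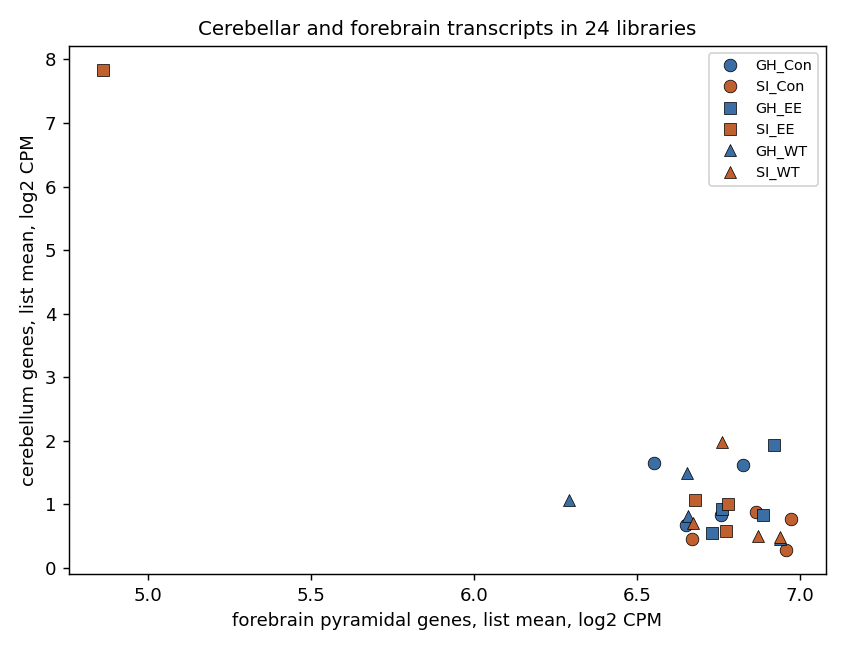
Mean log2 CPM of 16 cerebellar genes against that of 12 forebrain pyramidal genes in each of the 24 libraries. SI_EE 1 lies apart at 7.83 and 4.86.

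Social isolation without treatment was examined by setting SI_Con against GH_Con. Myelin and oligodendrocyte transcripts were lower in SI_Con than in GH_Con: 22 of 23 measured members had negative fold changes, and the list's mean was 6.35 ± 0.18 log2 CPM in SI_Con and 6.80 ± 0.17 in GH_Con. Trf, the iron carrier transferrin made by oligodendrocytes (chromosome 9, 103204001 to 103230444, minus strand), was at 237 ± 33.8 CPM against 389 ± 36.4 (log2 fold change −0.72, SE 0.15), and Mag, a myelin adhesion glycoprotein (chromosome 7, 30899176 to 30914873, minus strand), at 118 ± 14.8 against 193 ± 17.7. The list passed camera (adjusted p = 1.83e-14; adjusted p = 0.272 with an estimated correlation), and its exact permutation p was 0.0286, the smallest this design allows (adjusted 0.457). Of its members, 11 passed when adjusted over the list alone, among them Plekhh1 (−0.70), Gjc3 (−0.58), Tspan2, Ermn, Gjb1, Aspa and Ugt8a, and 0 over all genes. GH_EE and GH_WT also lay mostly below GH_Con, the shared reference. Per library the list mean was 6.64 to 7.02 in GH_Con, 6.25 to 6.79 in GH_EE and 6.35 to 6.81 in GH_WT. It was 6.10 to 6.48 in SI_Con, 6.26 to 6.865 in SI_EE and 6.43 to 6.74 in SI_WT. Isolation within EE or within the WT arm did not give a called myelin list with all libraries. Without SI_EE 1 the list passed camera within EE, but with isolated mice on average higher. How much of the difference between SI_Con and GH_Con lies in GH_Con cannot be told.

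Glial and immune lists lay on the same side. Oligodendrocyte precursor genes had 15 of 15 negative fold changes (camera adjusted p = 3.37e-05; adjusted p = 0.324 with an estimated correlation), with Enpp6, a marker of newly forming oligodendrocytes, at −0.68 and Cacng4 at −0.49. Homeostatic microglial genes had 14 of 14 negative (9.59e-06; adjusted p = 0.463 with an estimated correlation), plaque-associated microglial genes 21 of 24 and interferon response genes 21 of 24 (both 5.66e-05; adjusted p = 0.509 and 0.516 with an estimated correlation), and astrocyte markers 12 of 15 (0.00315; adjusted p = 0.509 with an estimated correlation). Nuclear oxidative phosphorylation genes were higher, with 82 of 84 positive (1.39e-13; adjusted p = 0.509 with an estimated correlation), as were circadian genes, with 14 of 17 (0.000139; adjusted p = 0.272 with an estimated correlation). In SI_Con 2 and SI_Con 3, of the 4 libraries of SI_Con, longer genes read lower, against GH_Con 2 alone in GH_Con. Without the 4 libraries of the series in which they did, oxidative phosphorylation genes were not called (0.0734), while the glial, immune and circadian lists were. GH_Con held 3 female libraries; with sex as a covariate the plaque-associated (0.000239), homeostatic (2.35e-05) and interferon lists (0.000676) kept their calls. Per1, a clock gene that also responds to light and stress hormone, was at 94.4 ± 28.1 CPM in SI_Con against 63.9 ± 3.60 (0.56, past the threshold when adjusted over the list alone). These 8 of the 14 lists that camera called stayed called in each of the 8 fits that leave out 1 library.

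The other 6 were each lost without at least 1 library. Higher glucocorticoid response (17 of 20 positive, 9.27e-05) and ribosomal protein genes (76 of 87, 4.08e-05) were no longer called without SI_Con 3 (adjusted p = 0.0648 and 0.323); adjusted p = 0.472 and 0.737 with an estimated correlation. Without the 4 libraries with lower long genes the ribosomal list (0.112) turned negative and was not called. Immediate early genes (23 of 28 positive, 0.00137; adjusted p = 0.509 with an estimated correlation) were not called without GH_Con 1 (0.0877) or SI_Con 4 (0.101). Blood genes, lower in SI_Con with 5 of 6 members past the threshold adjusted over the list alone (0.00914; adjusted p = 0.509 with an estimated correlation), were not called without GH_Con 4 (0.209) or SI_Con 1 (0.0606). Complement genes (10 of 14 negative, 0.0188; adjusted p = 0.516 with an estimated correlation) and striatal genes (16 of 17 negative, 0.0216; adjusted p = 0.737 with an estimated correlation) were also called. The complement call ended without GH_Con 1 (0.236), GH_Con 2 (0.0737), SI_Con 1 (0.0551) or SI_Con 4 (0.133), and the striatal one without GH_Con 2 (0.0737), SI_Con 1 (0.182), SI_Con 2 (0.226) or the 4 with lower long genes (0.247).

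Over all genes, edgeR called 0 for isolation, with 1330 at an unadjusted p under 0.05, a number that 6 of the 35 splits of these 8 libraries reached. DESeq2 called 33, limma-voom 0, the fit with surrogate variables 8, and the fit of these groups alone 1. The smallest p was that of Bap1, a deubiquitinase of histone H2A (chromosome 14, 31251450 to 31259944, plus strand), at 135 ± 7.27 CPM in SI_Con against 83.2 ± 2.66 (log2 fold change 0.69, SE 0.11, edgeR adjusted p = 0.0741). Then came Wipf1 (−0.56), Gpcpd1 (−0.85), Trf and Smyd1 (−1.63). The log2 fold changes of the genes given for each comparison were App −0.04, Thy1 −0.32, Cst7 −2.69, Trem2 −1.11, P2ry12 −0.28, Gfap −1.30, Mbp −0.34, Bdnf 0.07 and Fos 0.48.

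**Figure D2:**
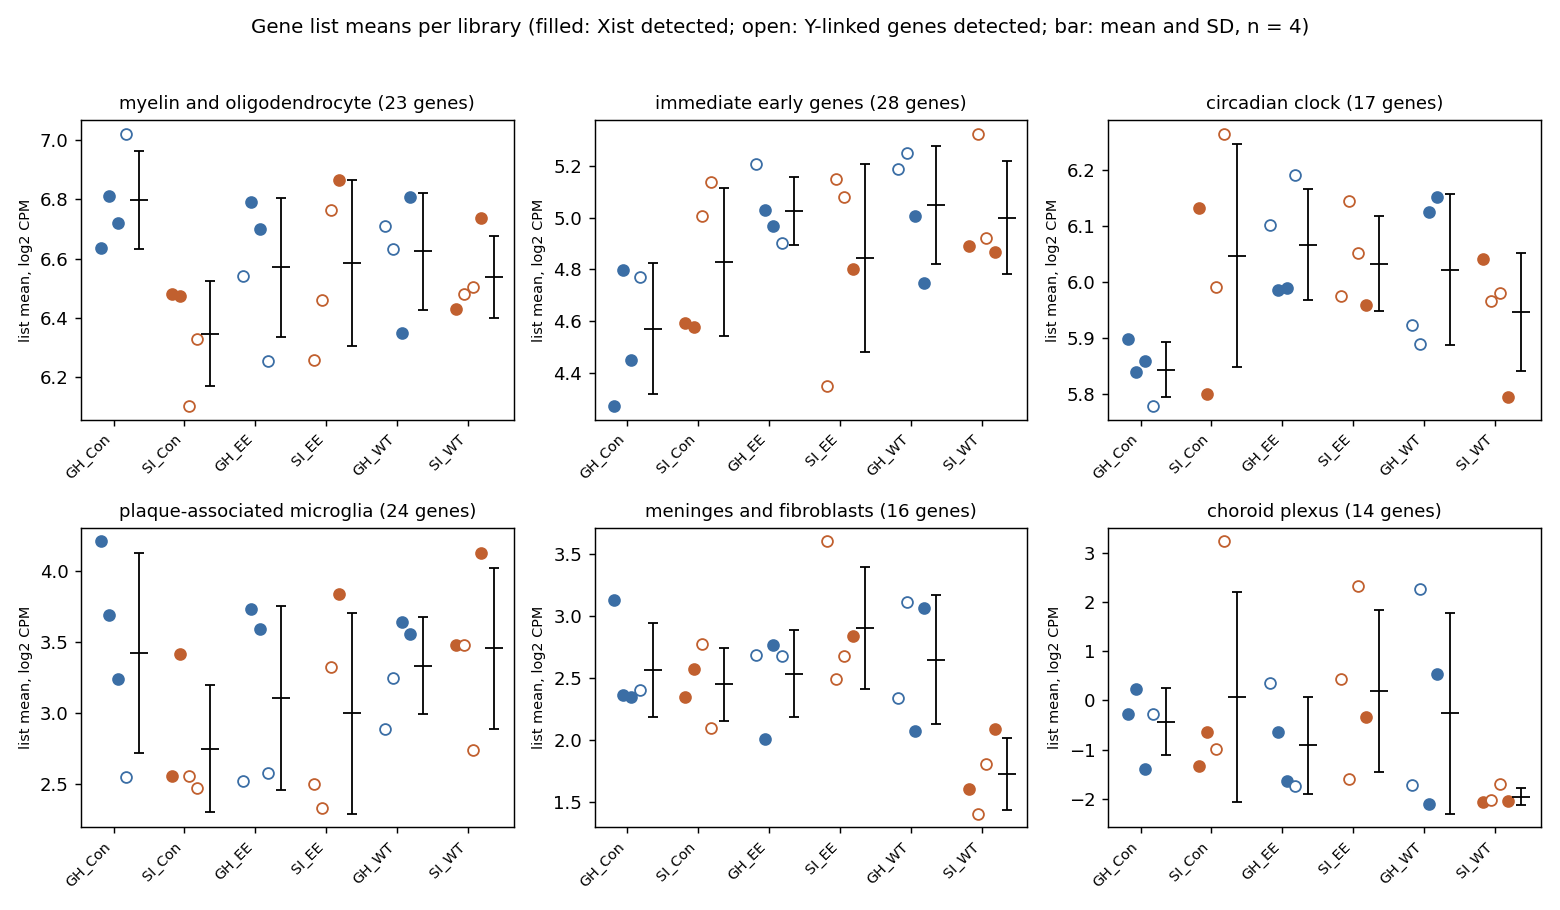
Mean log2 CPM of 6 gene lists (myelin and oligodendrocyte, immediate early, circadian, plaque-associated microglia, meninges, choroid plexus) in each library by group. Filled points are libraries with Xist, open points those with Y-linked genes, and bars give the group mean and SD (n = 4). Myelin genes averaged 6.35 in SI_Con and 6.80 in GH_Con.

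Enrichment in isolated mice, which the series title names beside resocialization, was SI_EE against SI_Con. Myelin genes were higher in SI_EE, with 19 of 23 positive (camera adjusted p = 8.17e-05; adjusted p = 0.730 with an estimated correlation). Library means of the list overlapped, at 6.26 to 6.865 log2 CPM in SI_EE and 6.10 to 6.48 in SI_Con, and its exact permutation p was not under 0.05. Of the myelin genes Trf (371 ± 39.6 against 237 ± 33.8 CPM, log2 fold change 0.65), Plekhh1 (0.59) and Gjc3 (0.41) passed when adjusted over the list alone. Interferon response genes were also higher, 22 of 24 (5.18e-05; adjusted p = 0.730 with an estimated correlation). Lower were the mitochondrially encoded genes (13 of 13 negative, 3.03e-05, exact permutation p = 0.0286, adjusted 0.774), nuclear oxidative phosphorylation genes (79 of 84, 7.69e-12) and ribosomal protein genes (84 of 87, 3.68e-12), each at an adjusted p = 0.730 with an estimated correlation. These 5 of 9 called lists stayed called without any 1 library. That leaves SI_Con 2 or SI_Con 3 in, both with lower long genes; without the 4 such libraries oxidative phosphorylation (0.384) and ribosomal protein genes (0.612) were not called. The other 4, higher reactive astrocyte (14 of 17), astrocyte marker (12 of 15), heat shock (18 of 22) and meningeal genes (13 of 16), were each lost in 3 to 5 of those 8 fits and had an adjusted p of 0.730 or above with an estimated correlation. Without SI_EE 1 the astrocyte markers had an adjusted p = 0.471 and the meningeal genes 0.222. With sex as a covariate heat shock genes were not called (0.134), interferon genes were (2.54e-09), and plaque-associated genes (0.425 without it) had 0.0148. Aqp4, the astrocyte water channel, was at 134 ± 74.8 against 67.6 ± 14.3 CPM and passed adjusted over the list alone. Homer3 (3.38) and Grm4 (1.69) also passed within their list, with SI_EE 1 far above the other libraries.

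edgeR called 0 genes for this contrast, with 2563 at an unadjusted p under 0.05 and a smallest adjusted p of 0.159. DESeq2 called 164, and SI_EE 1 was the highest library for 89 of them. limma-voom called 0, the fit with surrogate variables 9, and edgeR without SI_EE 2 called 91. Of those 91, 8 were genes of the cerebellar list, and SI_EE 1 stays in that fit. The smallest p belonged to Gm44777 (1.44), Plcd4 (0.78), Klhl28 (0.55), Gm20342 (1.01) and Nipal4 (0.81). App was at −0.07, Thy1 −0.22, Cst7 1.45, Trem2 0.26, P2ry12 −0.46, Gfap 0.81, Mbp −0.02, Bdnf 0.32 and Fos 0.33 (log2 fold changes, none past the threshold).

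In the WT arm of isolated mice, SI_WT against SI_Con, genes of the meninges and fibroblasts were lower: 16 of 16 members were negative, and the list's mean was 1.72 ± 0.29 log2 CPM against 2.45 ± 0.29 (camera adjusted p = 7.00e-10; adjusted p = 0.546 with an estimated correlation; exact permutation p = 0.0286, n = 4). Ogn, a small proteoglycan of fibroblasts (−1.41; chromosome 13, 49608046 to 49624501, plus strand), Slc13a4, a sulfate transporter (−1.49; chromosome 6, 35267957 to 35308131, minus strand), Ptgds (−0.93) and Fmod (−1.18) passed when adjusted over the list alone. Choroid plexus genes had 14 of 14 negative, 12 of them past the threshold adjusted over the list alone (7.66e-09; adjusted p = 0.621 with an estimated correlation). Ttr was at 4.66 ± 4.23 against 268 ± 496 CPM, the latter mostly SI_Con 4. The meningeal and choroid plexus lists, like the striatal one, are of tissue neighbouring the cortex. Here and in the comparisons below their level also depends on what was dissected along, which the labels do not give. Plaque-associated microglial genes were higher, 21 of 24 positive and a mean of 3.46 ± 0.57 against 2.75 ± 0.45 log2 CPM (4.75e-07; adjusted p = 0.621 with an estimated correlation; exact permutation p = 0.0571). Cst7, a cystatin of plaque-associated microglia, was at 5.75 ± 3.31 against 0.821 ± 1.07 CPM and did not pass. These 3 of 11 called lists stayed called without any 1 library.

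Homeostatic microglial genes (13 of 14 positive, 4.71e-05) and glucocorticoid response genes (18 of 20 negative, 1.47e-05) were lost without SI_Con 3 (adjusted p = 0.135 and 0.105), and interferon (24 of 24 positive, 2.71e-06) and myelin genes (19 of 23 positive, 6.18e-05) without SI_WT 4 (0.0827 and 0.0522); each had an adjusted p = 0.621 with an estimated correlation. Without the 4 libraries with lower long genes (SI_Con 2, SI_Con 3 and SI_WT 4 here) homeostatic microglial (0.124), interferon (0.0853) and myelin genes (0.580) were not called. Mural cell genes had 10 of 12 negative (0.0470; adjusted p = 0.636 with an estimated correlation) and kept the call in 2 of the 8 fits. Slc2a1, the glucose transporter of brain endothelium, was at −0.57 and passed adjusted over the list alone. edgeR called 0 genes, with 781 at an unadjusted p under 0.05, fewer than the 1018 expected by chance. DESeq2 called 2, limma-voom 1 and the fit with surrogate variables 1. The smallest p belonged to Mboat2 (−1.08), Nipal4 (0.78), Large2 (−2.53), Nelfb (−0.44) and Lepr (−1.32). The remaining log2 fold changes were App −0.02, Thy1 0.59, Cst7 2.79, Trem2 1.25, P2ry12 0.25, Gfap 0.96, Mbp 0.11, Bdnf 0.37 and Fos 0.20.

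Without isolation, enrichment (GH_EE against GH_Con) went with higher activity-dependent and clock genes. Both lists were also mostly higher in SI_Con and GH_WT than in GH_Con, the shared reference. Immediate early means per library were 4.27 to 4.80 in GH_Con, 4.58 to 5.14 in SI_Con, 4.90 to 5.21 in GH_EE and 4.75 to 5.25 in GH_WT. Circadian means were 5.78 to 5.90, 5.80 to 6.265, 5.99 to 6.19 and 5.89 to 6.15 in that order. A low GH_Con and an effect of enrichment cannot be told apart here. Of the immediate early genes 23 of 28 were positive, with a list mean of 5.03 ± 0.13 log2 CPM against 4.57 ± 0.26 (camera adjusted p = 1.79e-08; adjusted p = 0.390 with an estimated correlation; exact permutation p = 0.0286, n = 4, adjusted 0.305). Egr2 (12.1 ± 2.52 against 4.06 ± 2.05 CPM), Arc, which regulates glutamate receptor trafficking (297 ± 78.9 against 129 ± 35.8), Fos (32.1 ± 7.74 against 16.6 ± 8.06), Nr4a1 (0.87), Sik1 (0.83) and Tiparp (0.55) were the 6 members past the threshold adjusted over the list alone. Circadian genes had 13 of 17 positive (5.16e-05; adjusted p = 0.243 with an estimated correlation; exact permutation p = 0.0286), and Per2 (0.85), Bhlhe40 (0.61) and Per1 (0.53) passed within the list. Heat shock and unfolded protein genes had 20 of 22 positive (1.21e-07; adjusted p = 0.505 with an estimated correlation), among them Manf at 0.60. Mitochondrially encoded genes had 13 of 13 negative (1.79e-08; adjusted p = 0.414 with an estimated correlation), with mt-Nd6, which is encoded on the other strand than most, at 87.5 ± 9.61 against 151 ± 22.6 CPM, and ribosomal protein genes 80 of 87 negative (1.20e-06; adjusted p = 0.779 with an estimated correlation). These 5 of 8 called lists stayed called without any 1 library.

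Interferon genes (24 of 24 negative, 0.00319; 0.0307 with sex as a covariate) were lost without GH_Con 2 (adjusted p = 0.238) or GH_EE 1 (0.0873), myelin genes (20 of 23 negative, 0.000230) without GH_Con 4 (0.0529) or GH_EE 4 (0.0732), and blood genes without GH_Con 4 (0.258) or GH_EE 2 (0.204); they had an adjusted p of 0.764 or above with an estimated correlation. edgeR called 1 gene, Gm5514, a processed pseudogene (chromosome 19, 21937380 to 21938381, plus strand), at 20.3 ± 12.9 CPM in GH_EE against 0.740 ± 0.103 (log2 fold change 4.77, SE 0.60, adjusted p = 0.00137). It had 975, 1085 and 898 reads in GH_EE 1, 2 and 4, and 34 in GH_EE 3, within the 22 to 47 of all other libraries; the fit with surrogate variables (4.75), limma-voom (3.79) and the fit of these groups alone (4.78) did not call it. In all, 1286 genes had an unadjusted p under 0.05; DESeq2 called 26 genes, limma-voom 10, of which 7 were among those 26, and the groups alone 2. Next by p were Mphosph10 (0.56), 0610009L18Rik (−1.42), Gm9776 (−1.18) and Gm8355 (0.54). Of the genes always given, App was at 0.11, Thy1 −0.36, Cst7 −0.45, Trem2 −0.66, P2ry12 −0.05, Gfap −0.58, Mbp −0.33, Bdnf 0.08 and Fos 0.95.

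The WT arm without isolation, GH_WT against GH_Con, gave higher immediate early genes, which had 22 of 28 positive and a mean of 5.05 ± 0.23 against 4.57 ± 0.26 log2 CPM (camera adjusted p = 6.09e-11; adjusted p = 0.287 with an estimated correlation; exact permutation p = 0.0857, n = 4). The 8 members past the threshold adjusted over the list alone were Egr2 (1.54), Fos (1.25, 39.3 ± 11.8 CPM), Arc (1.41, 342 ± 106 CPM), Nr4a3 (1.41), Nr4a1 (0.89), Junb (0.75), Sik1 (0.74) and Tiparp (0.66). Circadian genes had 12 of 17 positive (0.000700; adjusted p = 0.287 with an estimated correlation); Per1 (chromosome 11, 69095217 to 69109960, plus strand) was at 111 ± 5.98 against 63.9 ± 3.60 CPM and passed within the list, as did Bhlhe40 (0.59). Glucocorticoid response genes had 17 of 20 positive (0.00166; adjusted p = 0.939 with an estimated correlation; exact permutation p = 0.0286). Mitochondrially encoded genes had 13 of 13 negative (8.27e-09; adjusted p = 0.397 with an estimated correlation; exact permutation p = 0.0286), and striatal genes 17 of 17, with a mean of 4.51 ± 1.19 against 5.53 ± 0.10 log2 CPM (1.11e-09; adjusted p = 0.642 with an estimated correlation), GH_WT 1 lying lowest. These 5 of 7 called lists stayed called without any 1 library. Striatal means were 2.995, 4.36, 5.865 and 4.83 log2 CPM in GH_WT 1 to 4, and 5.43 to 5.66 in GH_Con. Their level also depends on what was dissected along. The immediate early and circadian lists were also mostly higher in SI_Con and GH_EE, set against the same GH_Con libraries. Ribosomal protein genes (78 of 87 negative, 1.81e-05) were lost without GH_Con 2 (adjusted p = 0.229) and myelin genes (21 of 23 negative, 0.000762) without GH_Con 4 (0.206) or GH_WT 3 (0.255); both had an adjusted p = 0.994 with an estimated correlation.

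Slc17a6, the glutamate transporter of thalamic neurons, was at 76.4 ± 44.8 against 31.1 ± 4.02 CPM and passed within its list together with Ntng1 (1.26), in the group whose libraries 2 and 4 held thalamic transcripts. edgeR called 0 genes, with 696 at an unadjusted p under 0.05, fewer than the 1018 expected by chance. DESeq2 called 11, limma-voom 0 and the fit of these groups alone 2. Smallest by p were Per1 (0.79), Bap1 (0.52), Rgs16 (1.28) and Slitrk6 (3.51), both highest in GH_WT 2 and GH_WT 4, and Gm43294 (−1.89). App was at 0.06, Thy1 −0.22, Cst7 −0.57, Trem2 −0.30, P2ry12 0.02, Gfap −0.60, Mbp −0.18, Bdnf 0.11 and Fos 1.25.

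Isolation under enrichment, SI_EE against GH_EE, gave lower neuronal lists that rested on SI_EE 1, the library with cerebellar transcripts. Postsynaptic (33 of 41 negative, 0.000767), presynaptic (27 of 32, 0.000767), GABA receptor (14 of 15), cortical pyramidal (17 of 23), monoamine and peptide receptor (22 of 28), interneuron (19 of 26) and striatal genes (16 of 17) passed camera. Without SI_EE 1 their adjusted p-values were 0.0801, 0.0754, 0.0754, 0.149, 0.305, 0.754 and 0.858. Homeostatic microglial genes (13 of 14 negative, 0.00181) likewise had 0.133. Interferon genes were higher in SI_EE with 24 of 24 positive (0.000767) and were lost without SI_EE 4 (0.111). The adjusted p of these lists was 0.684 or above with an estimated correlation. Camera called 13 lists with all libraries. Without SI_EE 1 it called 4. Interferon and choroid plexus genes (0.0313) were among the 13, and myelin (0.0162) and oxidative phosphorylation genes (0.00245) were not. Without that library myelin means were 6.46 to 6.865 log2 CPM in SI_EE and 6.25 to 6.79 in GH_EE, on average higher in isolated mice. That is the opposite side to SI_Con against GH_Con. Oxidative phosphorylation means were 5.14 to 5.36 in SI_EE and 5.25 to 5.45 in GH_EE, on average lower. Of the 13, 0 stayed called without any 1 library. With sex as a covariate (SI_EE held 1 female and 3 male libraries) blood genes were not called (0.0920), while interferon (8.24e-08) and homeostatic microglial genes (0.00312) were. edgeR called 1 gene, Gm5514, at 0.906 ± 0.229 against 20.3 ± 12.9 CPM (log2 fold change −4.48, SE 0.59, adjusted p = 0.00285); limma-voom, the fit with surrogate variables, that of these groups alone and that without SI_EE 1 and with sex as a covariate called 0 genes, while DESeq2 called 23. At an unadjusted p under 0.05 there were 1771. Next by p were Gm20342 (1.07), 4933421O10Rik (0.90), 2310015A10Rik (1.31) and ENSMUSG00000121053 (1.27). Log2 fold changes were App −0.22, Thy1 −0.17, Cst7 −0.79, Trem2 −0.19, P2ry12 −0.69, Gfap 0.09, Mbp −0.02, Bdnf 0.31 and Fos −0.14.

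Isolation within the WT arm, SI_WT against GH_WT, gave lower meningeal genes, with 15 of 16 negative, 9 of them past the threshold adjusted over the list alone, and a mean of 1.72 ± 0.29 against 2.65 ± 0.52 log2 CPM (camera adjusted p = 5.71e-12; adjusted p = 0.311 with an estimated correlation; exact permutation p = 0.0571, n = 4). Dcn, the collagen-binding proteoglycan decorin, was at 2.74 ± 0.765 against 8.45 ± 3.79 CPM, with Slc13a4 at −1.78 and Aebp1 −1.38. Choroid plexus genes had 14 of 14 negative (1.03e-05) and blood genes 6 of 6 (0.000420), while heat shock genes had 18 of 22 positive (0.000289), each with an adjusted p = 0.498 with an estimated correlation. These 4 of 13 called lists stayed called without any 1 library. The meningeal mean was 3.12 and 3.07 in GH_WT 2 and GH_WT 4, 2.34 and 2.076 in GH_WT 1 and GH_WT 3, and 1.40 to 2.085 in SI_WT. Choroid plexus means were 2.27 and 0.535 in GH_WT 2 and GH_WT 4, −1.72 and −2.12 in GH_WT 1 and GH_WT 3, and −2.06 to −1.70 in SI_WT. Leaving out 1 library does not remove both GH_WT 2 and GH_WT 4. Ribosomal protein genes (84 of 87 positive, 1.49e-11), nuclear oxidative phosphorylation genes (75 of 84 positive) and mitochondrially encoded genes (13 of 13 positive) were lost without SI_WT 4 (adjusted p = 0.280, 0.0561 and 0.244), and striatal genes (16 of 17 positive, 6.30e-06) without GH_WT 1 (0.104). Endothelial genes had 13 of 16 negative (0.0352) and kept the call in 3 of the 8 fits, while astrocyte marker, oligodendrocyte precursor, glucocorticoid and mural cell genes, also lower, were each lost in 2 to 4 of them. These lists had an adjusted p of 0.498 or above with an estimated correlation. edgeR called 0 genes, with 1092 at an unadjusted p under 0.05; DESeq2 called 11 and limma-voom 0. The smallest p belonged to Gpr151 (−3.68), a habenular receptor, Bmp7 (−0.96), Slitrk6 (−3.53), Smtn (−0.53) and Wfikkn2 (−2.48). Gpr151 and Slitrk6 were high in GH_WT 2 and GH_WT 4, which held thalamic transcripts (10.2 and 6.45 CPM, 12.1 and 13.2 CPM), against 0.395 and 1.14 and 0.339 and 2.46 CPM in GH_WT 1 and GH_WT 3. App was at −0.12, Thy1 0.50, Cst7 0.67, Trem2 0.45, P2ry12 −0.05, Gfap 0.26, Mbp −0.05, Bdnf 0.33 and Fos −0.56.

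Set directly against each other in isolated mice, SI_EE and SI_WT differed in meningeal genes, higher in SI_EE with 15 of 16 positive, 12 of them past the threshold adjusted over the list alone, and a mean of 2.90 ± 0.49 against 1.72 ± 0.29 log2 CPM (camera adjusted p = 6.34e-14; adjusted p = 0.190 with an estimated correlation; fry adjusted p = 0.0212; exact permutation p = 0.0286, n = 4, adjusted 0.305). Slc13a4 was at 9.10 ± 2.85 against 1.86 ± 0.907 CPM, with Ogn at 1.93, Fmod 1.94 and Dcn 1.79. Choroid plexus genes had 14 of 14 positive (1.51e-06; adjusted p = 0.653 with an estimated correlation; exact permutation p = 0.0286) and reactive astrocyte genes 13 of 17 (0.000698; adjusted p = 0.642 with an estimated correlation; exact permutation p = 0.0286), with a mean of 2.43 ± 0.27 against 1.70 ± 0.24 and Cd109 at 2.42. Mitochondrially encoded genes had 13 of 13 negative (2.06e-06; adjusted p = 0.653 with an estimated correlation). These 4 of 10 called lists stayed called without any 1 library.

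Of the others, oxidative phosphorylation (78 of 84 negative) and ribosomal protein genes (84 of 87 negative) were lost without SI_WT 4 (adjusted p = 0.309 and 0.330), blood genes (6 of 6 positive) without SI_EE 2 (0.0573), homeostatic microglial genes (11 of 14 negative) without SI_EE 1 (0.147), and plaque-associated genes (18 of 24 negative) without SI_EE 1 (0.0920), SI_EE 2 (0.219) or SI_WT 4 (0.309). These had an adjusted p of 0.653 or above with an estimated correlation. Astrocyte markers, higher in SI_EE (camera adjusted p = 0.0257), were lost without SI_EE 1 (0.636), SI_EE 4 (0.0555), SI_WT 1 (0.112) or SI_WT 3 (0.135). They were not called with an estimated correlation. edgeR called 0 genes, with 2070 at an unadjusted p under 0.05; DESeq2 called 81, with SI_EE 1 the highest library for 53, and limma-voom 0. Smallest by p were Svil (0.85), Slc13a4 (2.29), Amotl2 (0.81), Ogn and Ltbp2 (6.86, 12.8 ± 24.9 CPM in SI_EE). The other values were App −0.05, Thy1 −0.81, Cst7 −1.34, Trem2 −0.99, P2ry12 −0.71, Gfap −0.15, Mbp −0.13, Bdnf −0.05 and Fos 0.12.

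Whether enrichment acted differently by housing was tested as an interaction, (SI_EE − SI_Con) − (GH_EE − GH_Con). The permutation p given here is for no housing difference in either arm, not for the interaction alone. Myelin genes had 21 of 23 positive (camera adjusted p = 1.92e-08; adjusted p = 0.536 with an estimated correlation), with a list difference of 0.47 (permutation p = 0.0767) and Trf (0.93), Gjb1 (0.81), Plekhh1 (0.78), Mag (0.66), Gjc3 (0.64) and Fa2h (0.59) past the threshold adjusted over the list alone. Interferon genes had 24 of 24 positive (7.13e-08), astrocyte markers 13 of 15 (0.00261; Sox9 at 1.27) and blood genes 6 of 6 (0.00106). Immediate early genes had 21 of 28 negative (0.000126; Sik1 at −1.28), circadian genes 13 of 17 (0.00132; Per1 at −0.84) and oxidative phosphorylation genes 76 of 84 (2.15e-06). These lists, 7 of the 16 called, stayed called in each of 16 fits that leave out 1 library, and had an adjusted p of 0.536 or above with an estimated correlation. Without the 4 libraries with lower long genes the oxidative phosphorylation list was not called (0.368) and the ribosomal one turned positive (0.0424). Interferon (5.39e-10) and blood genes (6.36e-05) stayed called with sex as a covariate. GH_Con enters both interactions with housing, so its high myelin and low immediate early and circadian values are part of them. Glucocorticoid genes were lost without SI_Con 3 (0.127), and the other 8 calls (adjusted p = 0.0402 to 0.0476) ended in 5 to 9 of the 16 fits. edgeR called 0 genes, with 1576 at an unadjusted p under 0.05; DESeq2 called 27 and limma-voom 0. Smallest by p were Gm5514 (−4.87, edgeR adjusted p = 0.0717), Gm20342 (1.36), Plscr1 (2.71), Phldb1 (1.12) and Vasn (−1.11). App was at −0.18, Thy1 0.14, Cst7 1.90, Trem2 0.92, P2ry12 −0.41, Gfap 1.39, Mbp 0.31, Bdnf 0.24 and Fos −0.62.

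The interaction of the WT arm with housing was negative for glucocorticoid response genes, 19 of 20 (camera adjusted p = 5.72e-07; adjusted p = 0.491 with an estimated correlation; permutation p = 0.0216, adjusted 0.631). The permutation p is again for no housing difference in either arm. Sgk1, a hormone-induced kinase (−1.56), Ddit4 (−1.28), Nfkbia (−1.19), Map3k6 (−1.65) and Errfi1 (−0.64) passed when adjusted over the list alone. Meningeal genes had 15 of 16 negative (9.28e-07), choroid plexus genes 14 of 14 with 12 past the threshold adjusted over the list alone, and circadian genes 13 of 17 (Per1 at −0.95). Positive were myelin genes (22 of 23, 5.86e-07), plaque-associated (20 of 24, 7.73e-05) and homeostatic microglial genes (13 of 14), mitochondrially encoded genes (13 of 13) and striatal genes (16 of 17, 3.58e-07). These lists, 9 of the 10 called, stayed called in each of 16 fits that leave out 1 library, and had an adjusted p of 0.491 or above with an estimated correlation. Homeostatic microglial genes were not called without the 4 libraries with lower long genes (0.0671). The striatal, meningeal and choroid plexus lists also depend on what was dissected along. Immediate early genes (20 of 28 negative) were lost without GH_Con 1 (0.0649) or SI_Con 4 (0.0655). edgeR called 0 genes, with 921 at an unadjusted p under 0.05, fewer than the 1018 expected by chance. DESeq2 called 1 and limma-voom 0. Smallest by p were Large2 (−3.28), Zfp961 (3.10), ENSMUSG00000119988 (3.10), Per1 and Cpne7 (−1.74). App was at −0.08, Thy1 0.81, Cst7 3.36, Trem2 1.55, P2ry12 0.23, Gfap 1.56, Mbp 0.29, Bdnf 0.26 and Fos −1.04.

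Genes of antigen presentation, neurotrophic signalling, amyloid processing, olfactory bulb and the sex chromosomes passed camera in 0 of the 10 comparisons; their smallest adjusted p-values were 0.0680, 0.244, 0.104, 0.267 and 0.551.

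Reversal of the isolation difference was tested by correlating, across 20354 genes, the fold changes of SI_Con against GH_Con with those of SI_EE against SI_Con. Pearson's r was −0.453 where 20 simulated runs with no effect gave −0.499, since both contrasts share the SI_Con libraries, and the covariance was −0.0995 against −0.0883. With the SI_Con libraries divided between the contrasts r was −0.00515 and the covariance −3.85e-05 (one-sided exact permutation p of the covariance = 0.445). For SI_WT against SI_Con, r was −0.538 against −0.499 simulated, and the covariance −0.102 against −0.0867. With divided libraries r was −0.0115 and the covariance −0.00206 (one-sided exact permutation p of the covariance = 0.393). Genes are not independent replicates, and neither correlation differed from that of reassigned libraries (one-sided exact permutation p = 0.626 and 0.301).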

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

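The tests on SI_EE 1 were chosen after its values were seen, and so were the counts of other splits, apart from those for enrichment in GH mice and for isolation under enrichment.

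Of 276 group values tested, 27 held a library whose gap to its nearest neighbour exceeded Dixon's 95% bound for 4 samples, where chance gives about 14. SI_WT 4 gave 7 of them: ribosomal protein genes took 1.70% of its reads and averaged 6.99 log2 CPM, Mbp was at 814 CPM, and the postsynaptic (6.43), presynaptic (7.88), GABA receptor (6.51) and monoamine and peptide receptor (2.17) list means were low. SI_EE 1 gave 5: App at 763 CPM and low list means for interneurons (4.45), GABA receptors (6.18), cortical pyramidal layers (4.92) and striatum (2.58). GH_Con 2 was high for ribosomal protein genes (1.31% of reads, list mean 6.58), SI_Con 2 for Cst7 (2.40 CPM) and plaque-associated genes (3.42), SI_Con 4 for choroid plexus (3.24) and neurotrophic genes (4.94), SI_WT 2 for astrocyte markers (7.09) and immediate early genes (5.33), and GH_Con 1 for meningeal genes (3.13). GH_Con 4 was high for interneuron genes (5.18), GH_EE 4 for reactive astrocyte genes (2.26) and SI_WT 3 for choroid plexus genes (−1.70). Low were SI_WT 3 for oligodendrocyte precursor genes (4.10), GH_EE 2 for meningeal genes (2.01) and GH_EE 3 for Gm5514 (0.965 CPM against 25.9 to 27.9 in the other 3).

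Cerebellar genes averaged 7.83 log2 CPM in SI_EE 1 and at most 1.98 elsewhere, with Cbln3 at 868 CPM and Car8 at 1063 CPM; 9 of the 16 listed genes have a median of at least 1 CPM in the other libraries, and 0 are in the fixed lists. A library made wholly of cerebellum would have to lack cortical pyramidal transcripts, but the median forebrain pyramidal gene stood at 21.5% of its median in the other libraries. Enrichment in isolation as the source is argued against by the other 3 SI_EE libraries, whose median list mean lay 0.179 log2 CPM above that of the 20 libraries of the other groups. Cerebellar tissue in the dissected piece stays open: the median gene of the cortical layer list stood at 49.5%, next to the bound of 50% set for it. A swap with a sample from outside the series was not tested.

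In 8 of 10 comparisons the real count of called genes was 0, which every split of the samples reaches, so their splits do not test chance. The highest other count was 0 for isolation (35 of 35 splits as large), 436 for enrichment and 1178 for the WT arm in isolated mice, and 1 each for the WT arm in GH mice, isolation in the WT arm and enrichment against the WT arm, all 35 of 35. For enrichment in GH mice 6 of 35 splits, and for isolation under enrichment 7 of 35, gave at least the real count of 1, with 1 the highest other, so chance is not excluded for that count. At an unadjusted p under 0.05 the real split gave 1286 genes against at most 747 and 1771 against at most 1723 there. In the 8 other comparisons another split gave more: 2278 against 1330 for isolation (6 of 35 splits as large), 5252 against 2563 (8) and 4880 against 781 (19) for enrichment and the WT arm in isolated mice, 935 against 696 (4) for the WT arm in GH mice, 1730 against 1092 (7) for isolation in the WT arm, 4336 against 2070 (12) for enrichment against the WT arm, and 3586 against 1576 (7 of 50) and 2488 against 921 (15 of 50) for the interactions. For the interactions with housing 50 of 50 splits were as large, with 25 (enrichment) and 1 (WT arm) the highest others. Splits for the interactions shuffled housing within each arm, so they do not test the interaction alone. The splits that called 436 and 1178 genes put SI_Con 2 and SI_Con 3 on 1 side, with SI_EE 1 and SI_EE 2, and with SI_WT 2 and SI_WT 4, which points to a structure of the samples apart from their groups.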

How the results depend on the processing

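The sex covariate, the fits without SI_EE 1 or without the 4 libraries with lower long genes, the surrogate variables and the permutation of list means were chosen after seeing the data. RLE factors, either count filter, the replicate block and the sex covariate moved no count of called genes by over 1.5 times. DESeq2 called 33, 164, 2, 26, 11, 23, 11, 81, 27 and 1 genes in the order of the report's comparisons, where edgeR called 0 apart from 1 for enrichment in GH mice and 1 for isolation under enrichment. Some DESeq2 calls had implausibly large log2 fold changes. For isolation Gm10593 was at 22.64 and Gm4631 at 23.43, where edgeR gave 8.37 and 9.16 (edgeR unadjusted p = 0.0492 and 0.028). Others, such as Bap1 (0.69 in both), had the same fold change. limma-voom called 1 for the WT arm in isolated mice, 10 for enrichment in GH mice and 0 for isolation under enrichment. Surrogate variables gave 8 (isolation), 9 and 1 (enrichment and WT arm in isolated mice) and 0 for both contrasts that call Gm5514. The compared groups alone gave 1 (isolation), 2 (enrichment in GH mice), 2 (WT arm in GH mice) and 0 (isolation under enrichment); without SI_EE 1 and with sex, enrichment in isolated mice had 1 and isolation under enrichment 0. The cause of these differences was not tested.

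Leaving out 1 library gave 0 to 1 genes for isolation, 0 to 91 for enrichment in isolated mice (91 without SI_EE 2, of which DESeq2 shared 51), 0 to 1 for the WT arm there, 1 to 1 for enrichment in GH mice, 0 to 0 for the WT arm there, 1 to 3 for isolation under enrichment, 0 to 1 in the WT arm, 0 to 1 for enrichment against the WT arm, and 0 to 1 and 0 to 0 for the interactions. Of the 91 genes, 8 were of the cerebellar list. Lists called by camera numbered 12 to 16, 6 to 15, 8 to 13, 7 to 12, 7 to 9, 4 to 14, 9 to 15, 8 to 17, 8 to 18 and 9 to 13 in the same order of comparisons. In each comparison 0 lists were called with an estimated correlation, by fry or by the permutation, apart from 1 by fry for enrichment against the WT arm. An unadjusted permutation p under 0.05 was reached by 2, 1, 2, 3, 2, 0, 3, 3, 0 and 1 of 32 lists, in the same order of comparisons. Without SI_EE 1, 4 lists were called for isolation under enrichment, 2 of them among the 13 called with it. Without the 4 libraries with lower long genes 5 lists were called for the WT arm in isolated mice and 16 for enrichment against the WT arm, and other counts moved by under 1.5 times. Correlations with the isolation fold changes ran from −0.538 to −0.360 (enrichment) and −0.634 to −0.475 (WT arm) without 1 library, and were −0.00515 and −0.0115 with the SI_Con libraries divided, which removes the shared values. Of 2934 refits of the genes given for each comparison, Gm5514 included, 2741 kept direction and side of the threshold, 129 changed sign without being called, 7, all of Gm5514, lost and 57 gained a call, and 0 called values reversed.

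The replicate numbers do not pair the samples: of 60 same-number pairs 4 had deviations correlated over 0.1 (median −0.0131), and 4 of 24 libraries correlated best with their own number. With the number as a block the counts of called genes and lists stayed within 1.5 times. At a depth of at least 33683587 reads per library, 48% of simulated 2-fold changes were recovered in the isolation comparison.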

Other observations

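All tests here were chosen after the values were seen, except the 3 tests of explanations for the difference by sex, which were fixed before their results.

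Plaque-associated microglial genes differed between the 12 samples with Xist, called female here, and the 12 with Y-linked genes, called male. The list's mean was 3.59 log2 CPM in the female and 2.77 in the male samples (male minus female −0.82, SE 0.16, with group in the model), lower in male samples in 6 of 6 groups and for 23 of 24 genes, 14 of which passed when adjusted over the list alone. The permutation p within groups was 4.82e-05, the smallest that 20736 assignments can give (adjusted 0.0015 over 31 lists), the adjusted p was 0.0186 with an estimated correlation, and the difference was −0.90 to −0.77 when any 1 library was left out. Trem2, a microglial lipid receptor, was at 17.6 CPM in the female and 8.95 in the male samples (1.87-fold; folds by sex are from the model with group), Cst7 at 5.71 and 1.51 (4.45-fold), and Clec7a and Itgax differed 4.25-fold and 4.06-fold. Homeostatic microglial genes (−0.41, SE 0.13, 13 of 14) and interferon genes (−0.62, 24 of 24, 19 past the threshold adjusted over the list alone) were also lower in the male samples (both adjusted permutation p = 0.0218). Heat shock genes (0.24, 22 of 22, adjusted permutation p = 0.0218) and blood genes (1.79, 6 of 6, adjusted permutation p = 0.0105) were higher there. edgeR called 12 genes by sex, 7 higher in female and 5 in male samples, with 1268 at an unadjusted p under 0.05. Besides Xist, Y-linked genes and the X-linked Eif2s3x they included the immune genes Lag3 (2.02-fold), Bst2 (2.04-fold), Iigp1 (2.37-fold) and Tbxas1 (1.74-fold), all higher in the female samples.

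The human APP entry was at 3172 ± 780 CPM in the 12 female and 2196 ± 1069 in the 12 male samples (permutation p = 0.0407). Its level as the whole cause of the difference in plaque-associated genes is argued against, since 85.3% of the difference stayed with that entry in the model. A higher share of microglia alone would move both microglial lists alike, but the plaque-associated list fell further than the homeostatic one by 0.41 (SE 0.15, −2.67 SE). The short-gene bias of some libraries left 98.8%. Sex of the mice, which the labels do not give, stays a candidate explanation, and GH_Con held 3 female libraries and SI_EE 3 male, so part of the group values of the microglial, interferon, heat shock and blood lists may come from it; with sex as a covariate the lists called for isolation numbered 13.

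Within the male samples the human APP entry and the plaque-associated list mean were correlated (n = 12, Pearson's r = 0.638, permutation p = 0.0222, adjusted 0.0889 over 4 relations; Spearman's rho = 0.783, permutation p = 0.00404, adjusted 0.0162), and r was 0.723 without the 2 samples farthest from the median. Within the 12 female samples r was 0.290 (permutation p = 0.373) and rho 0.217 (permutation p = 0.502). Reactive astrocyte genes gave r = −0.0303 in the female and −0.482 in the male samples, neither past the threshold.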
